A study of Mus musculus with 10 samples.

How the data were processed

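RNA from embryonic day 5.5 mouse embryos was measured on 10 Affymetrix arrays, 5 of type MOE430A and 5 of type MOE430B, which carry mostly different probe sets. The labels give 3 kinds of sample. Ad is the anterior distal fragment, cut to hold the fluorescent anterior visceral endoderm and the epiblast under it. Pp is the posterior proximal fragment, cut from proximal visceral endoderm and epiblast on the opposite side. The last kind is the whole embryo. Each array type holds 2 Ad arrays, 2 Pp arrays and 1 whole-embryo array, and the RNA had been linearly amplified before hybridisation.

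The deposited values are probe set intensity, in arbitrary units on a linear scale, made by the authors with MAS5 per the submitters' processing notes. The MAS5 version, its scaling target and any floor are not given in the sources used here. The values were tested before use: array medians lay between 590 and 644 on MOE430A and between 56.8 and 61.0 on MOE430B, so the arrays of each type had already been brought to about the same scale. A value of exactly 1, as a floor would leave, made up 5.69% to 6.13% of each MOE430B array and at most 0.132% of each MOE430A array. Each MOE430B array also held 5 to 11 values below 1, which a strict floor at 1 would not leave. The 3' to 5' signal ratio of the Gapdh control probe sets was 1.40 to 1.60 on MOE430A and 1.19 to 1.49 on MOE430B. That of the Actb control probe sets on MOE430A was 3.69 to 4.50 in the fragments and 5.87 in the whole embryo, and on MOE430B it was 3.51 to 3.79 and 4.22. An array value has no count behind it. Beyond the signal over background, the number of arrays limits the precision.

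Each array type was analysed alone in R 4.3.3 with limma 3.58.1. The 64 control probe sets of each type were left out. A pseudocount equal to the 20th percentile of all values of that type, 247 on MOE430A and 10.5 on MOE430B, was added before the log2. Probe sets were kept when their mean log2 value over the 5 arrays lay above the 40th percentile, which matches a signal of 463 on MOE430A and 37.0 on MOE430B. This left 13575 of 22690 probe sets (8707 genes) on MOE430A and 13506 of 22575 (6923 genes) on MOE430B. Each array was then centred on its median over kept probe sets. A linear model with the 3 kinds of sample was fitted with lmFit and eBayes, with 2 residual degrees of freedom. The comparisons were Ad minus Pp and the mean of Ad and Pp minus the whole embryo. The single whole-embryo array was assumed to vary like the fragments. All tests were two-sided, and the threshold was a Benjamini-Hochberg adjusted p of 0.05 over the kept probe sets of that array type and comparison. Every adjusted p given for a gene comes from limma. Folds come from the fitted log2 differences, and the pseudocount draws them towards 1. Where a group mean lies below the filter signal, the size of the fold depends on the pseudocount, so for named genes the levels are given without a fold. Signal levels are the deposited values, as mean ± SD over n arrays.

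Probe sets were named from the platform annotation. On MOE430A 20393 probe sets had exactly 1 gene symbol, 691 had several and 1606 had none. On MOE430B the counts were 14674, 245 and 7656. Gene identifiers matched the RefSeq gene names of assembly GRCm38.p6 for 20364 and 14499 probe sets, with 0 symbols changed, and that assembly was used only for names.

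The rule for named genes, the tests, the gene lists and all but 3 of the alternatives were set before the data were examined. In Ad against Pp, the rule names the 10 genes (MOE430A) or 5 genes (MOE430B) with the largest difference each way among those past the threshold, with 1 probe set per gene, the brightest. Brightest means the highest mean log2 value over the 5 arrays. Where too few passed, the rule fills the places with genes whose Ad and Pp arrays lay at least 2-fold apart without overlap, on the centred log2 scale. For fragments against the whole embryo it names 5 genes each way. It also names any measured member of 18 gene lists holding 350 genes, with the anterior and posterior lists always given. Those lists cover anterior and distal visceral endoderm, posterior and primitive streak, general visceral endoderm, epiblast, extraembryonic ectoderm, ectoplacental cone and giant cells, parietal endoderm, and maternal blood and decidua. The others cover Nodal, Bmp and Tgf-beta signalling, Wnt signalling, cell migration and actin, ribosomal proteins, oxidative phosphorylation, glycolysis, cell cycle, cholesterol synthesis, immediate early and stress genes, and lysosome and endocytosis. Lists with at least 3 measured genes were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation. A further list of 20 decidual stroma genes was written after the whole-embryo result had been seen, and its member Esr1 is also named by the rule on MOE430B.

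The alternatives were no centring, quantile normalization, cyclic loess, no pseudocount, a pseudocount at the 40th percentile, no filter, a filter at the 60th percentile, an intensity trend in eBayes, the replicate number as a block, 1 probe set per gene, list tests with an estimated correlation or without Cer1, and each Ad and Pp array left out in turn. With 1 array left out, its group holds 1 array and the spread comes from the other pair alone. Such a fit says nothing of the spread within the group left with 1 array. The replicate block fits used only the 4 fragment arrays and left 1 residual degree of freedom. The labels do not say that equal numbers belong together. Across probe sets the difference within the Ad pair correlated with that within the Pp pair at -0.242 on MOE430A and -0.0413 on MOE430B. These values give no sign of such a pairing. The method was tested on simulated data of the same size. The probe sets varied independently, each with the same spread in all kinds of sample, drawn from the fitted prior. In the real arrays the Pp pair varied more than the Ad pair (SD of log2 differences 0.188 against 0.126 on MOE430A). The planted differences also gave more calls than the real data (145 against 23 on MOE430A), which eases the threshold. The differences were planted after the pseudocount had been added, so the simulated folds are fitted folds. The same fold in deposited signal gives a smaller fitted fold and would be found less often. The rates need not carry over to the real arrays. On MOE430A the method found 48.9% of simulated 1.41-fold and 97.7% of 2-fold differences between Ad and Pp, with 7 false calls among 145. On MOE430B it found 0% and 36.2%, with 4 false calls among 113. For fragments against the whole embryo it found 91.3% of 2-fold differences on MOE430A and 25.5% on MOE430B. A simulated list of 15 genes, shifted by 0.3 on the log2 scale between Ad and Pp, was tested with camera. Its unadjusted p was 6.64e-17 on MOE430A and 2.99e-05 on MOE430B at the preset correlation, and 0.0131 and 0.0468 with an estimated one. With an estimated correlation 0 of 100 unshifted lists fell under 0.05 on each array type. A list that fails that test is not shown to be unchanged. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.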

Results

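The study set out to find genes with more RNA in the anterior distal fragment (Ad) than in the posterior proximal fragment (Pp) of the embryo at embryonic day 5.5, when the anterior visceral endoderm is moving away from the distal tip. The embryos carried a fluorescent reporter under a Cer1 promoter, which guided the dissection. Signal was measured on 5 arrays of MOE430A (Ad replicates 1 and 2, Pp replicates 1 and 2, 1 whole embryo) and on 5 arrays of MOE430B (Ad replicates 3 and 4, Pp replicates 3 and 4, 1 whole embryo). The labels do not say that the replicates came from separate embryos, so the p-values measure only the spread between these samples. On MOE430A the Ad pair correlated at a Spearman rho of 0.987 across probe sets and the Pp pair at 0.972, while each fragment correlated with the whole embryo at 0.919 to 0.936. On MOE430B these values were 0.977, 0.956 and 0.918 to 0.945. These correlations are across probe sets, which are not independent replicates.

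Ad fragments held more RNA of regulators of the anterior visceral endoderm. Lefty1, which encodes a secreted Nodal antagonist, was 4.58-fold higher in Ad (5574 ± 1295, SD, n = 2) than in Pp (949 ± 53.1, n = 2; adjusted p = 0.0136). The homeobox gene Hesx1 was higher (1678 ± 221 against 408 ± 2.10; adjusted p = 0.0136), and the LIM homeobox gene Lhx1 2.53-fold (2302 ± 51.3 against 716 ± 57.9; adjusted p = 0.00894). The forkhead gene Foxa2 was 2.17-fold higher (2125 ± 254 against 794 ± 61.5; adjusted p = 0.0237). Shisa2, an antagonist of Wnt and Fgf receptors, was 2.34-fold higher (adjusted p = 0.0312), and the Wnt receptor gene Fzd8 was also higher (mean 1027 against 403; adjusted p = 0.0415). These 6 genes rose among the 13 measured of the anterior and distal visceral endoderm list, and 11 rose adjusted over the list alone. The list median was 1.06 on the log2 scale, with 12 of 13 members positive, and the list test gave adjusted p = 4.45e-20, or adjusted p = 0.255 with an estimated correlation. Without Cer1 the list test gave adjusted p = 2.22e-18.

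The other 7 members did not pass. Hhex, a homeobox gene of the same tissue, was at 2531 ± 463 in Ad and 1016 ± 2.60 in Pp (adjusted p = 0.0527), Dkk1, a secreted Wnt antagonist, at 3272 ± 1395 and 1258 ± 70.9 (adjusted p = 0.252), and Otx2 at 2593 ± 197 and 1217 ± 445 (adjusted p = 0.232). Hhex passed with no centring (adjusted p = 0.0317), no pseudocount (0.0438), the filter at the 60th percentile (0.0400), an intensity trend (0.0434) and the replicate block (0.0374). It also passed with the replicates paired crosswise (0.0295), an alternative added after seeing the data. Log2 differences were 0.41 for Amot, 0.02 for Sfrp5 and -0.02 for Sfrp1, which turned positive with no centring (0.04) and under cyclic loess (0.00087). Cer1 serves here as a check of the labels, since its promoter marked the dissected tissue. Its brightest probe set did not pass (1.45-fold, adjusted p = 0.0860), and among settings that kept all arrays it passed only with no centring (0.0471). The other Cer1 probe set was higher in Ad (3676 ± 7.87 against 286 ± 3.36, adjusted p = 0.00019). Its mean log2 value was lower, but its deposited signal in Ad was above that of the first (mean 1472). Sfrp1 also had a fainter probe set at 1.34-fold (adjusted p = 0.207), and Lhx1 had another at 1.15-fold (adjusted p = 0.463).

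**Figure D1:**
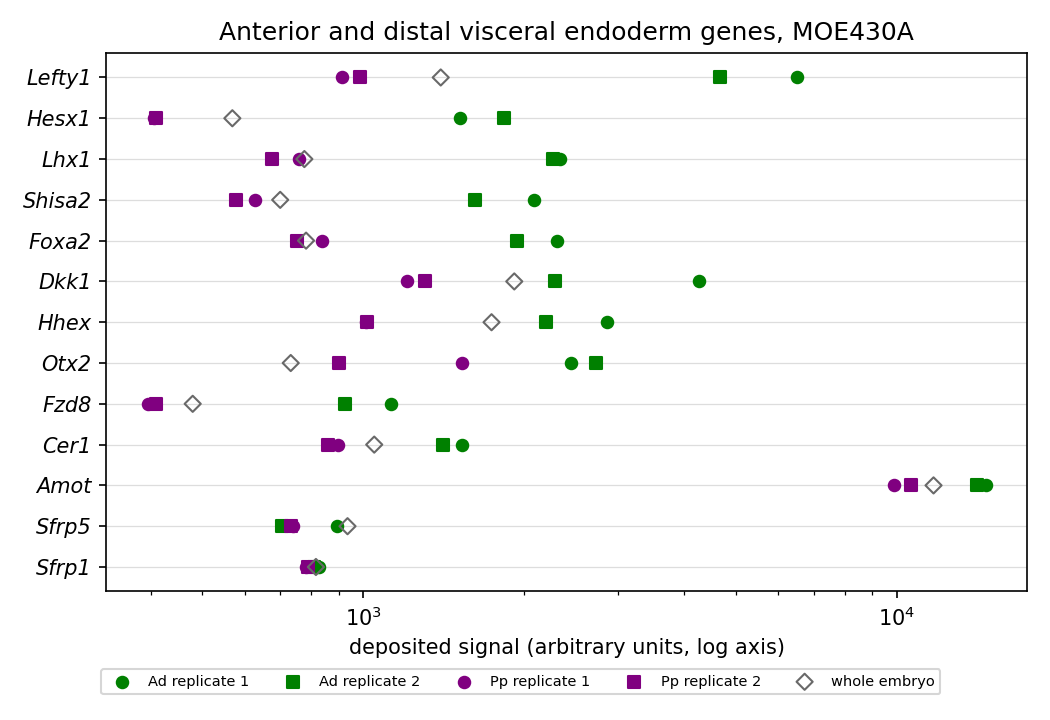
Deposited signal (arbitrary units, log axis) of the 13 measured genes of the anterior and distal visceral endoderm list on the 5 MOE430A arrays, each gene by its brightest probe set; points are single arrays. Both Ad arrays of Lefty1, Hesx1, Lhx1, Shisa2, Foxa2 and Fzd8 lie to the right of both Pp arrays, while the Sfrp1 and Sfrp5 points lie together.

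Outside that list, the genes with the largest rise in Ad by their brightest probe set were Pkdcc, a secreted tyrosine kinase (1942 ± 173 against 341 ± 95.7; adjusted p = 0.0136), and Hkdc1, a hexokinase family member (2.38-fold, 3411 ± 124 against 1218 ± 26.0; adjusted p = 0.00894). Pilrb1 (2.11-fold), the sulfotransferase gene Chst15 (2.10-fold) and the pepsinogen gene Pga5 (1.98-fold) followed, with adjusted p of 0.0194, 0.0136 and 0.0151. A fainter probe set of Smim14 was 2.36-fold higher (adjusted p = 0.0194), against 1.66-fold for its brightest (adjusted p = 0.0335). Tfec, a basic helix-loop-helix transcription factor, was lower in Ad (243 ± 59.6 against 821 ± 63.1; adjusted p = 0.0238). Its Ad mean lay below the filter signal. Id2, a target of Bmp signalling, was at 244 ± 27.3 in Ad and at 1020 and 2781 in the Pp arrays, and did not pass (adjusted p = 0.180).

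On MOE430A, 23 of 13575 probe sets passed between Ad and Pp, 22 higher in Ad (18 genes and 1 probe set with no name) and 1 lower, with fitted folds from 1.61 to 7.02; 1600 had an unadjusted p under 0.05. At least 2-fold apart without overlap were 13 probe sets, 10 higher and 3 lower in Ad, against 0 and 0 in the other 2 splits of these 4 arrays into pairs; for 2 arrays against 2, chance alone separates 33.3% of probe sets without regard to size. The number of calls depended on which array was left out. It fell without either Ad array and rose without either Pp array, with the spread taken from the pair that stayed. Adjusted p of the genes that the naming rule gave as passing, by their brightest probe sets, lay between 0.130 (Lefty1) and 0.436 (Fzd8) without Ad replicate 1, and between 0.146 (Hesx1) and 0.232 (Tfec) without Ad replicate 2, where of these Lefty1 alone kept its call (0.0361). The other Cer1 probe set kept its call without Ad replicate 1 (0.0367) and without Ad replicate 2 (0.0268), while the 2 Smim14 probe sets had adjusted p between 0.248 and 0.483. Of the 23 calls, 19 were kept with the replicate block (24 calls), 18 with no filter (19 calls) and 17 with the filter at the 60th percentile (25 calls). The calls of Shisa2, Fzd8 and Tfec ended with no filter (adjusted p = 0.0707, 0.0753 and 0.0598), and that of Fzd8 also with the larger pseudocount (adjusted p = 0.0673).

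Posterior genes leaned the other way, each by little. Mixl1, a homeobox gene of the primitive streak, was at 552 ± 83.8 in Ad and 958 ± 25.4 in Pp (log2 difference -0.66, adjusted p = 0.0907). Evx1 and the Nodal co-receptor gene Tdgf1 had log2 differences of -0.40 and -0.33. Of the 8 measured members of the posterior and primitive streak list, 0 passed in limma (Nodal, Wnt3a, Eomes, Cfc1 and Snai1 lay between -0.14 and -0.09) and 3 fell adjusted over the list alone. All 8 were negative except that Eomes, at -0.12, went to 0.00199 without Pp replicate 2. The list median was -0.13 (adjusted p = 0.000448, or adjusted p = 0.298 with an estimated correlation).

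Extraembryonic ectoderm genes were higher in Pp replicate 2 than in the other fragments. Elf5, a trophoblast transcription factor, was at 2432 in Pp replicate 2, 601 in Pp replicate 1 and 2194 in the whole embryo, with an Ad mean of 318 ± 33.6 (n = 2). Bmp4 was at 2359, 573 and 1595, and Hand1 at 1248, 471 and 4014. Of 18 measured members 0 passed in limma and 0 passed adjusted over the list alone; 17 were negative in Ad minus Pp, with a median of -0.20 (adjusted p = 0.000136, or adjusted p = 0.672 with an estimated correlation). Without Pp replicate 2 the list call ended (adjusted p = 0.142).

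Genes of cholesterol synthesis leaned lower in Ad as a group (adjusted p of the list = 1.67e-06, or adjusted p = 0.255 with an estimated correlation). The squalene synthase gene Fdft1 had a log2 difference of -0.46 and the sterol demethylase gene Cyp51 one of -0.61 (adjusted p = 0.145 and 0.187). All 13 measured members were negative with a median of -0.30; 0 passed in limma, and 5 fell adjusted over the list alone. The parietal endoderm list leaned towards Ad: 8 of 10 were positive with a median of 0.28, led by the laminin genes Lamc1 (0.61) and Lamb1 (0.47). None of those 10 passed in limma and 5 rose adjusted over the list alone (adjusted p of the list = 7.48e-05, or adjusted p = 0.255 with an estimated correlation). Of 13 glycolysis genes, 11 were negative and 0 passed, over the list alone too (median -0.09; adjusted p = 0.0347, or adjusted p = 0.672 with an estimated correlation). This glycolysis call ended without Ad replicate 2 (adjusted p = 0.0648), without Pp replicate 2 (adjusted p = 0.216) and under quantile normalization (adjusted p = 0.0562).

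No list call was made for the other 11 tested lists. Wnt signalling came nearest (16 genes, adjusted p = 0.0578; median -0.00 and mean 0.19): Fzd8 rose, and 5 rose and 1 fell adjusted over the list alone, with Porcn at 1.02 and Dkk1 at 1.10. Of 22 Nodal, Bmp and Tgf-beta genes Lefty1 rose, and 3 rose and 3 fell adjusted over the list alone (adjusted p = 0.866). The 22 general visceral endoderm genes had a median of -0.08 while the test leaned up (adjusted p = 0.897); 3 rose and 1 fell adjusted over the list alone. The 17 epiblast genes had a median of -0.01 (1 fell adjusted over the list alone; adjusted p = 0.897). Adjusted p was 0.880 for maternal blood and decidua, 0.120 for cell migration and actin (1 rose adjusted over the list alone) and for lysosome and endocytosis, 0.314 for cell cycle, 0.892 for immediate early and stress genes, and 0.897 for ribosomal proteins and for oxidative phosphorylation. For epiblast, ribosomal protein and oxidative phosphorylation genes the test also leaned up with a median and mean below 0. Of the ectoplacental list only Plac1 was measured (log2 difference -0.06). Of 17 lists tested, 6 passed at the preset correlation and 0 with an estimated correlation, where 3 had an unadjusted p under 0.05. With an estimated correlation a simulated shifted list reached an unadjusted camera p of only 0.0131. The 0 calls there do not show that the lists are unchanged.

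On MOE430B the largest named difference was in Fzd5, a Wnt receptor, 8.74-fold higher in Ad (3537 ± 498, n = 2) than in Pp (375 ± 61.6, n = 2; adjusted p = 0.00420). Sema6d, a transmembrane semaphorin, was 7.27-fold higher (762 ± 109 against 90.4 ± 15.5; adjusted p = 0.00466), and the potassium channel gene Kcnj5 was at 137 ± 5.48 against 19.9 ± 3.70 (adjusted p = 0.00654). The predicted genes Gm9558 (215 ± 29.5 against 35.6 ± 1.82; adjusted p = 0.00501) and Speer4cos (126 ± 41.9 against 17.5 ± 1.94; adjusted p = 0.0440) were also higher. Edem3, which acts in protein degradation from the endoplasmic reticulum, was lower in Ad (19.2 ± 4.43 against 176 ± 18.1; adjusted p = 0.00466). The activin antagonist gene Fst (102 against 396, adjusted p = 0.0539), the Wnt potentiator gene Rspo3 (117 against 432, adjusted p = 0.0637) and Maf (121 against 331, adjusted p = 0.106) were separated by at least 2-fold and did not pass. Ddah1 did not pass either (adjusted p = 0.358). It was at 491 ± 28.4 in Ad, at 957 and 2836 in the Pp arrays and at 3723 in the whole embryo. Its 2-fold separation held only after centring. With the replicate block Fst, Rspo3 and Maf passed (adjusted p = 0.0183, 0.00318 and 0.0416). That fit pairs arrays by number, though the labels do not say that equal numbers belong together. Fst and Rspo3 also passed with the larger pseudocount (0.0268 and 0.0294, with Maf at 0.0471) and the filter at the 60th percentile (0.0346 and 0.0394). They passed with an intensity trend too (0.0263 and 0.0333), and Fst passed with no centring (0.0482). Ddah1 and Maf had other probe sets with smaller differences, the nearest to 0 at -0.04 and 0.01, and the other Rspo3 probe set was at 0.04. On MOE430A another Fzd5 probe set was 1.39-fold higher in Ad (adjusted p = 0.179), and the other Sema6d probe sets on MOE430B had log2 differences of -0.17 and -0.55.

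In all, 15 of 13506 probe sets passed on MOE430B, 14 higher in Ad (11 genes and 3 with no name) and 1 lower, with fitted folds from 2.94 to 23.6; 1405 had an unadjusted p under 0.05. The largest difference was in a probe set with no gene name, which went from 88.1 ± 17.6 in Pp to 2425 ± 161 in Ad. At least 2-fold apart without overlap were 28 probe sets, 23 higher and 5 lower, against 0 and 2 in the other 2 splits. The limma calls went to 0 without Ad replicate 3 and to 0 without Ad replicate 4, and to 123 (93 higher, 30 lower) and 68 (58 higher, 10 lower) without Pp replicates 3 and 4. With no filter 2 calls were left, and Fzd5, Sema6d, Gm9558 and Edem3 had adjusted p = 0.0584, Kcnj5 0.0698 and Speer4cos 0.312. Without Ad replicate 3 or 4 the first 4 of these had adjusted p between 0.0792 (Fzd5) and 0.130 (Gm9558), while Kcnj5 and Speer4cos were removed by the filter. Speer4cos lost its call with no pseudocount (0.0549) and under quantile normalization (0.0547).

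The Wnt signalling list leaned towards Ad on MOE430B: 7 of 8 measured genes were positive with a median of 0.52, Fzd5 rose and 5 rose adjusted over the list alone (adjusted p = 7.24e-05, or adjusted p = 0.718 with an estimated correlation). It shares Dkk1 (1.42), Sfrp1 (1.13) and Sfrp5 (0.59) with the anterior list. Those 3 are the anterior genes measured there, and of them 0 passed and 3 rose adjusted over the list alone (median 1.13; adjusted p = 0.000222, or adjusted p = 0.718 with an estimated correlation). The other 10 tested lists, general visceral endoderm, epiblast, extraembryonic ectoderm, Nodal, Bmp and Tgf-beta signalling, migration, ribosomal, oxidative, glycolysis, cell cycle and lysosome genes, each had adjusted p = 0.790, and 0 of their genes passed in limma. Of these, 1 epiblast gene rose and 1 Nodal, Bmp and Tgf-beta gene fell adjusted over the list alone. Mean and median differed in sign for cell cycle (-0.09 and 0.02) and lysosome genes (0.06 and -0.00038). No posterior gene was measured on MOE430B, and 1 or 2 genes were of the ectoplacental, parietal endoderm, maternal, cholesterol and immediate early lists, none of which passed.

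The whole embryo was hybridised, per the labels, for normalization, and it also allows the fragments to be set against the intact tissue. On MOE430A the fragments (n = 4) held more RNA of Rbp4, a retinol carrier, at 2.42-fold (3998 ± 1094 against 1556 in the whole embryo; adjusted p = 0.00397) and of Afp, a fetal serum protein, at 2.13-fold (5580 ± 1148 against 2596; adjusted p = 0.00254). Igfbp2 (2.21-fold), Rbpms (2.17-fold) and Otx2 (2.17-fold) were also higher, with adjusted p of 0.00189, 0.00122 and 0.0357. Prl8a2, a prolactin family gene of the decidua, the maternal tissue around the embryo, was lower in the fragments (331 ± 155 against 6063; adjusted p = 0.00137), and Ctla2a was 12.7-fold lower (725 ± 622 against 11198; adjusted p = 0.0235). Tac2 was 10.6-fold lower (adjusted p = 0.0107), and S100a6 (361 ± 135 against 6450; adjusted p = 0.00218) and Rgs2 (428 ± 79.5 against 6578; adjusted p = 0.000538) were lower too. The call of Otx2 ended with no filter (adjusted p = 0.0617), without Ad replicate 1 (adjusted p = 0.113) and without Ad replicate 2 (adjusted p = 0.147).

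Epiblast genes leaned towards the fragments. Of 17 epiblast genes 8 rose, and 11 rose adjusted over the list alone, with Tdgf1 at 1.97-fold, Fgf4 at 1.90-fold, the amino acid transporter gene Slc7a3 at 1.89-fold and Pou5f1 at 1.73-fold (median 0.30; adjusted p = 0.000152, or adjusted p = 0.526 with an estimated correlation). Of 13 anterior visceral endoderm genes 6 rose and 7 rose adjusted over the list alone (median 0.40; adjusted p = 0.00194, or adjusted p = 0.526 with an estimated correlation). Of 8 genes of the posterior and primitive streak list, Tdgf1 and Cfc1 rose, both Nodal co-receptors, and 3 rose adjusted over the list alone (median 0.26; adjusted p = 0.0464, or adjusted p = 0.526 with an estimated correlation). The posterior call ended without Pp replicate 2 (adjusted p = 0.0557), with no pseudocount (adjusted p = 0.0522) and with gene means (adjusted p = 0.0527), an alternative added after seeing the data.

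Lists of extraembryonic and maternal genes leaned the other way. Of 18 extraembryonic ectoderm genes, Hand1 (4.73-fold lower, 658 ± 394 against 4014; adjusted p = 0.0203) and Ets2 (684 ± 199 against 1687; adjusted p = 0.0468) fell, and the same number fell adjusted over the list alone (median -0.20; adjusted p = 0.000473, or adjusted p = 0.526 with an estimated correlation). In the parietal endoderm list 6 of 10 genes fell, and 8 adjusted over the list alone: Vim 3.22-fold, Lamc1 1.98-fold, the collagen chaperone gene Serpinh1 1.87-fold, Col4a2 1.76-fold, Col4a1 and Sparc (median -0.72; adjusted p = 6.27e-07, or adjusted p = 0.327 with an estimated correlation). These encode an intermediate filament and matrix proteins that stromal cells make too. Of 10 maternal blood and decidua genes 3 fell, Prl8a2, Igfbp4 (4.38-fold) and Hoxa10 (389 ± 23.0 against 1887), also adjusted over the list alone (median -0.22; adjusted p = 0.000473, or adjusted p = 0.327 with an estimated correlation). Its blood genes Hbb-b2, Slc4a1 and Cd52 had log2 differences of -0.02, -0.04 and 0.02. Another Des probe set was 7.95-fold lower in the fragments (adjusted p = 0.000269), while the brightest was not (1.08-fold; adjusted p = 0.430).

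Lists of actin and lysosome genes leaned the same way. Of 18 cell migration and actin genes 5 fell, Actn1 1.91-fold, Flna 1.55-fold, Arpc2, Vcl and Abi1, and 5 adjusted over the list alone (median -0.22; adjusted p = 0.000473, or adjusted p = 0.327 with an estimated correlation). Of 16 lysosome and endocytosis genes Psap (2.93-fold) and Lamp2 (2.20-fold) fell, and 2 adjusted over the list alone (median -0.20; adjusted p = 0.000573, or adjusted p = 0.526 with an estimated correlation). The other 9 tested lists were not called. General visceral endoderm had adjusted p = 0.0739, with Afp, Rbp4 and Apoa1 higher and 4 up and 1 down adjusted over the list alone. Nodal, Bmp and Tgf-beta signalling had adjusted p = 0.284 with 4 genes up, Wnt signalling 0.653 with Fzd7 and Porcn up, and cell cycle 0.400 with 2 up (Cdk4, Ccne1) and 2 down (Mki67, Rrm2). Over each of these lists alone, 5, 3 and 7 genes rose and 0, 0 and 3 fell. Cholesterol synthesis had adjusted p = 0.537 with Fdft1 up (0 adjusted over the list alone) and immediate early and stress genes 0.191 with Ier2 up and Ier3 down. For ribosomal proteins, oxidative phosphorylation and glycolysis adjusted p was 0.400, 0.720 and 0.653, with 0 genes past limma's threshold. The measured ectoplacental gene, Plac1, fell 1.60-fold (adjusted p = 0.00690). Of 17 lists tested 8 passed at the preset correlation and 0 with an estimated correlation, where 1 had an unadjusted p under 0.05.

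**Figure D2:**
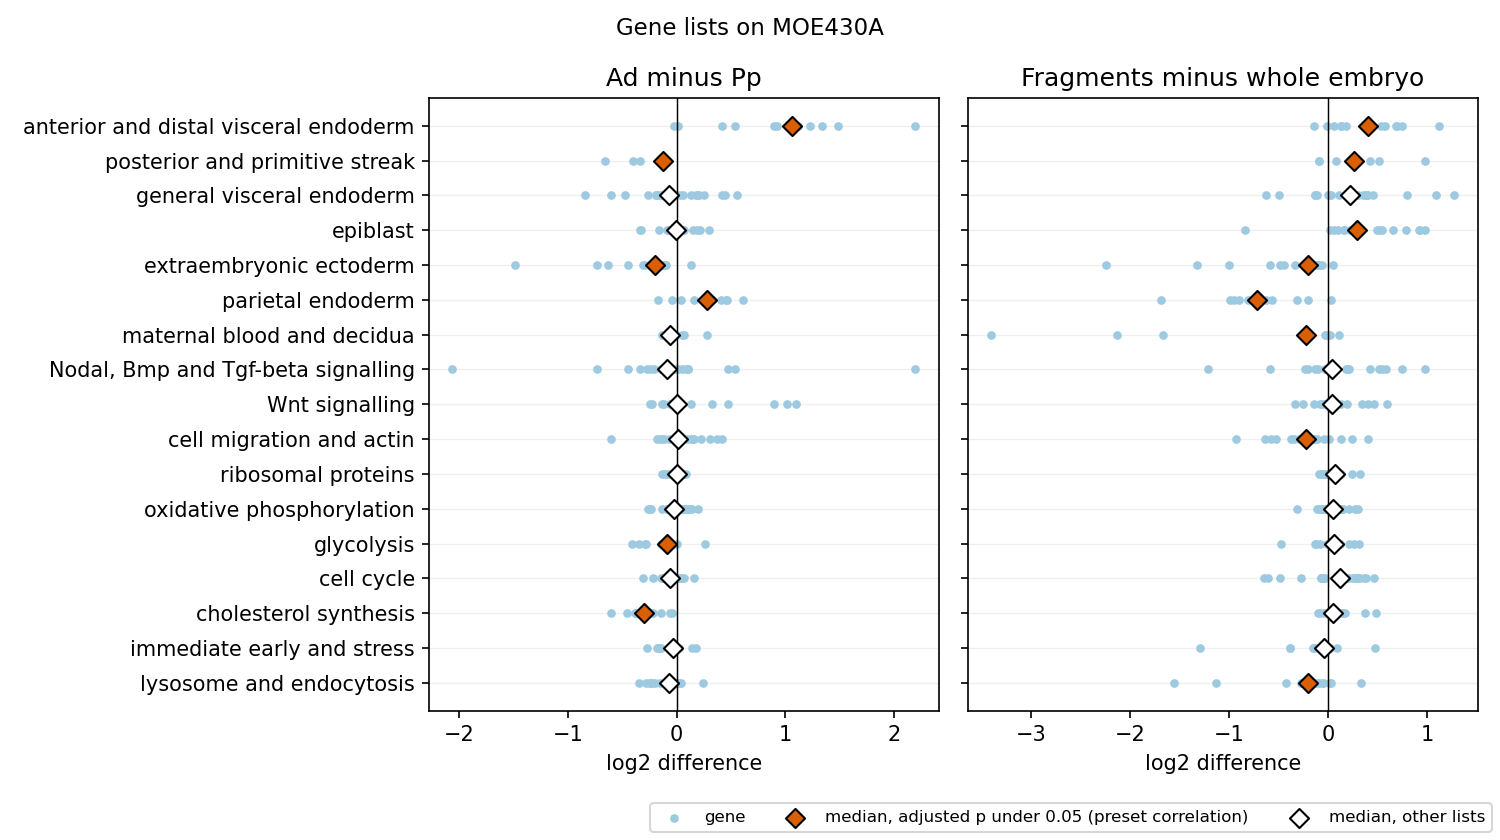
Log2 differences of list genes on MOE430A for Ad minus Pp (left) and fragments minus whole embryo (right); each point is 1 gene, diamonds are list medians, filled where the list test passed at the preset correlation. The anterior list has the largest median on the left (1.06) and the parietal endoderm list the lowest on the right (-0.72).

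Between fragments and whole embryo, 1320 of 13575 probe sets passed on MOE430A, 624 higher and 696 lower in the fragments, with folds from 1.24 to 12.7; 3699 had an unadjusted p under 0.05. The share higher in the fragments, 47.3%, went to 25.9% with no centring (333 higher, 951 lower), to 31.0% under cyclic loess (353 higher, 785 lower) and to 33.6% with no filter. Without Ad replicate 1 or 2 the calls were 277 and 264, with 11.6% and 11.4% higher, and without Pp replicate 1 or 2 they were 3093 and 3496, with 57.1% and 56.4% higher. The 3' to 5' signal ratio of the Actb control was 5.87 in the whole-embryo array and 3.69 to 4.50 in the fragments.

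On MOE430B, Esr1, an estrogen receptor gene, was 34.6-fold lower in the fragments (n = 4; 55.1 ± 33.2 against 1999 in the whole embryo; adjusted p = 0.0118), Tdo2, which breaks down tryptophan, 33.5-fold (46.8 ± 27.8 against 1751; adjusted p = 0.00568), and Hand2, a progesterone target in the uterus, 15.8-fold (133 ± 15.4 against 2223; adjusted p = 0.00123). Rgs2, Fosl2 and Gas7 were 21.5-fold, 19.7-fold and 18.2-fold lower (adjusted p = 0.00153, 0.00205 and 0.00175). Fainter probe sets on MOE430B were at 36.2 ± 3.31 against 70.7 for Esr1 (adjusted p = 0.0726), 1.43-fold lower for Rgs2 (adjusted p = 0.443) and 1.39-fold higher for Gas7 (adjusted p = 0.245), and the log2 difference was -0.57 for Hand2 (adjusted p = 0.191). On MOE430A the log2 difference was 0.15 for Esr1 (adjusted p = 0.282), 0.04 for Fosl2 (adjusted p = 0.767) and -1.11 for Tdo2 (adjusted p = 0.00117). The fragments were higher in Mael (3.68-fold), Spry4 (3.58-fold) and Utf1, a chromatin factor of pluripotent cells (3.38-fold, 380 ± 64.3 against 103; adjusted p = 0.00546). Other MOE430B probe sets were at 1.54-fold for Spry4 (adjusted p = 0.114) and 1.03-fold for Utf1 (adjusted p = 0.932). Zfhx3 (74.3 ± 15.9 against 4.42; adjusted p = 0.00576) and Galnt10 (95.9 ± 32.3 against 24.1; adjusted p = 0.0349) were also higher. Their whole-embryo values lay below the filter signal, and their probe sets on MOE430A did not pass (log2 differences 0.22 and -0.13 for Zfhx3, 0.10 for Galnt10). Of 5 epiblast genes Utf1 and Etv5 rose, and 4 rose and 1 fell adjusted over the list alone (median 0.85; adjusted p = 0.0191, or adjusted p = 0.776 with an estimated correlation). In the 11 other tested lists adjusted p lay between 0.201 and 0.916. Members that passed there were Psap and Npc2 of the lysosome list, Sfrp5 of the anterior and Wnt lists and Bmpr2 of the Nodal, Bmp and Tgf-beta list, all lower in the fragments. The measured ectoplacental gene, Adm, fell 4.31-fold (adjusted p = 0.00420). The call of Esr1 ended with no filter (adjusted p = 0.0596), as did those of Mael (0.0762), Spry4 (0.0604) and Galnt10 (0.121), the last also under quantile normalization (0.0613). Without Ad replicate 3 adjusted p was 0.0855 for Mael and 0.0693 for Spry4, and without Ad replicate 4 it was 0.0749, 0.0858 and, for Galnt10, 0.0685.

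Of 13506 probe sets 307 passed on MOE430B, 59 higher and 248 lower in the fragments, with folds from 1.78 to 34.6; 2222 had an unadjusted p under 0.05. The share higher in the fragments was 19.2%, and 4.59% with no filter. Without Ad replicates 3 and 4 the calls were 113 and 98, with 4.42% and 1.02% higher, and without Pp replicates 3 and 4 they were 659 and 1177, with 37.2% and 49.9% higher.

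**Figure D3:**
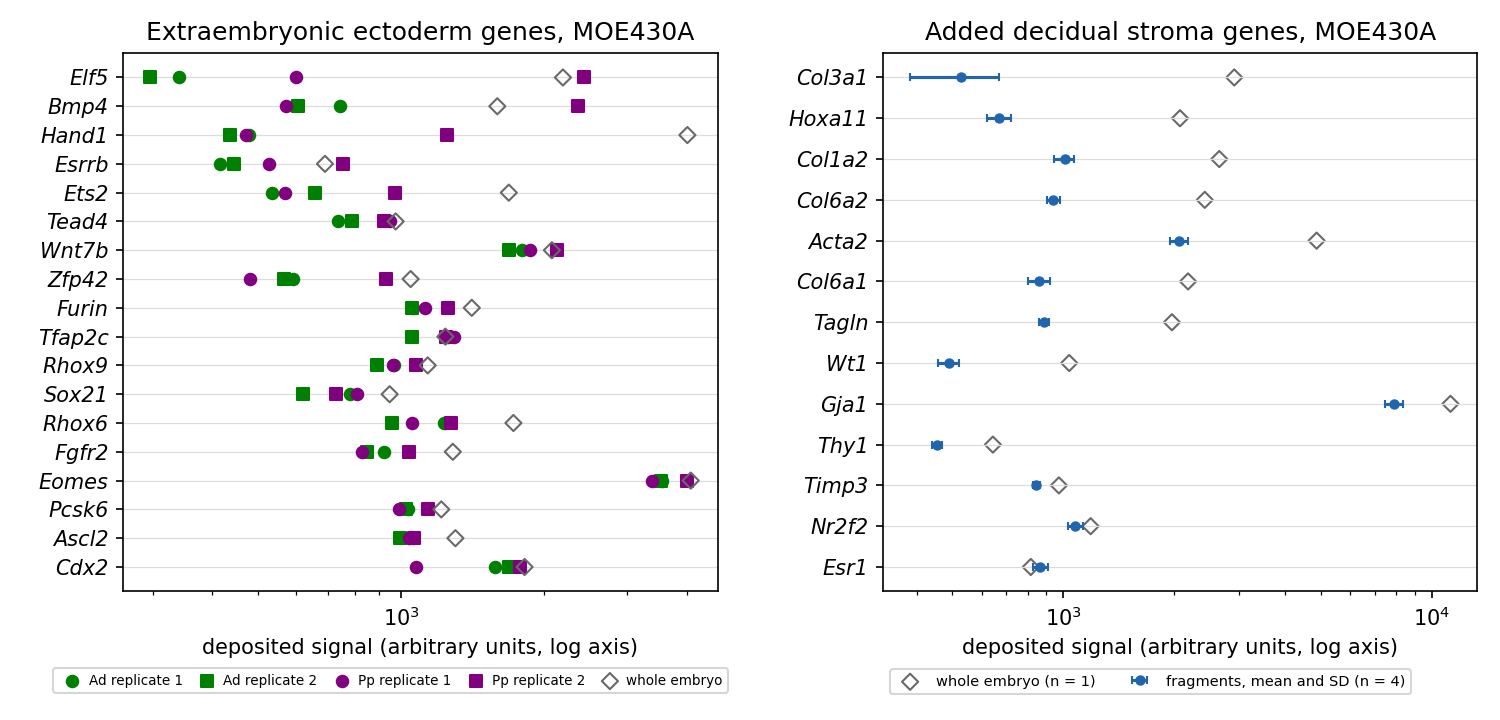
Deposited signal (arbitrary units, log axis) on MOE430A: left, the 18 extraembryonic ectoderm genes on each array; right, the 13 measured genes of the added decidual stroma list as mean and SD of the 4 fragments and the single whole-embryo value. Pp replicate 2 reaches 2432 for Elf5, near the whole embryo at 2194, and the whole embryo reaches 2910 for Col3a1 against 527 in the fragments.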

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

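Of the tests here, the crossed replicate block, the fit on fragment arrays only and the lists as gene means were chosen after the results had been seen. Between Ad and Pp on MOE430A the 23 calls became 46 with no centring (43 higher, 3 lower) and 46 with replicates paired crosswise (36 higher, 10 lower), all 23 kept in both, and 1 to 818 when 1 array was left out. By construction, leaving out an Ad array leaves the Pp pair (SD of log2 differences 0.188) to give the spread, and leaving out a Pp array leaves the Ad pair (0.126). On MOE430B (SD 0.349 and 0.244) the 15 calls became 30 with the pseudocount at the 40th percentile, 2 with no filter, 26 with the filter at the 60th percentile, 30 with an intensity trend, 28 with the replicate block and 27 with 1 probe set per gene, and 0 to 123 when 1 array was left out. The filter choices and 1 probe set per gene changed how many probe sets were tested; for the other settings the cause was not tested. Separated probe sets on MOE430A, 13, became 21 with no pseudocount, 8 with the larger pseudocount and 15 to 47 without 1 array, and on MOE430B, 28, they became 48 to 118 without 1 array. Between fragments and whole embryo, leaving out 1 array gave 264 to 3496 calls on MOE430A (1320) and 98 to 1177 on MOE430B (307), where no filter gave 196. With an estimated correlation the anterior list of Ad minus Pp had adjusted p = 0.255 and the extraembryonic ectoderm list of fragments minus whole 0.526; in the other 22 tests of these 2 lists under other settings, and in 8 with 1 array left out, direction and side of the threshold held. The sign turned only in genes that did not pass: Sfrp1 (main value -0.02) was 0.0437 with no centring, 0.000872 under cyclic loess and 0.00421 with no filter, Sfrp5 (0.02) ranged from -0.10 (without Ad replicate 1) to 0.14 without 1 array, and Eomes (-0.12) from -0.24 to 0.00199 (without Pp replicate 2). Of the other values of named genes, 538 kept direction and side of the threshold, 18 lost and 19 gained the call in settings that kept all Ad and Pp arrays. The block fits and the fit on fragment arrays only, counted here, leave out the whole embryo. Simulated 2-fold differences between Ad and Pp, planted after the pseudocount, were found in 36.2% of cases on MOE430B and in 97.7% on MOE430A. Their noise was drawn from the fitted prior (prior SD 0.159 on MOE430B against 0.0786 on MOE430A). These rates therefore reflect the wider spread of MOE430B and hardly its lower signal. Whether the wider spread comes from the lower signal was not tested.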

Other observations

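The correlations between array types, the values by array given next, the further decidual genes, the tests on extraembryonic ectoderm genes in Pp replicate 2, and the tests of the cholesterol list without that array and against visceral endoderm were chosen after the results had been seen. Further genes passed between Ad and Pp outside the naming rule. On MOE430B the insulin receptor substrate gene Irs4 was 3.96-fold higher in Ad (4746 ± 223 against 1135 ± 160, n = 2 each; adjusted p = 0.0133), Tgfbr3, a co-receptor for Tgf-beta and inhibin, 2.94-fold (adjusted p = 0.0321), and the forkhead gene Foxq1 3.35-fold (adjusted p = 0.0440). Lhx1os, a transcript beside Lhx1, was 4.25-fold higher (adjusted p = 0.0122), as were Akr1c19 (3.43-fold) and the zinc transporter gene Slc39a2 (3.07-fold). On MOE430A the others were Smim14, Tmem109, the aromatic amino acid decarboxylase gene Ddc (1.71-fold), Fam107b, the ribonuclease gene Rnase4 (1.62-fold) and the chromogranin gene Chga (943 ± 110 against 389 ± 16.2). With the replicate block the calls of Fam107b, Rnase4 (adjusted p = 0.0643 each), Chga (0.0547) and the brightest Smim14 probe set (0.0579) ended, and that of Chga also with no filter (0.0686) and with the larger pseudocount (0.0673). Without Ad replicate 1 or 2 the 6 genes had adjusted p between 0.248 and 0.574, with Chga removed by the filter without Ad replicate 1. The 6 genes of MOE430B lost the call with no filter (0.130 to 0.312), without Ad replicate 3 (0.220 or more) and without Ad replicate 4 (0.116 to 0.604). Tgfbr3, Foxq1, Akr1c19 and Slc39a2 also lost it with no pseudocount (0.0703 to 0.0996) and under quantile normalization (0.0508 to 0.0688).

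After the filter 98 probe sets were kept on both array types. Across them Ad minus Pp correlated at Pearson's r = 0.694 and fragments minus whole at 0.913. The difference between the Ad pair on MOE430A correlated with that on MOE430B at 0.737, the Pp pair at 0.231. Over the 2058 genes measured on both array types, by the brightest probe set on each, the correlations were lower. In the same order they were 0.255, 0.339, 0.131 and 0.120. Probe sets are not independent replicates, and the labels do not say whether the array types shared RNA. Of the genes called on MOE430A, 2 were measured on MOE430B, both with the same sign; of those called on MOE430B, 5 were measured on MOE430A, 3 with the same sign. Among the fragments on MOE430A, Ad replicate 2 had the highest Prl8a2 (564), Ctla2a (1646) and Tac2 (945); Pp replicates 1 and 2 were at 241 and 267 for Prl8a2, and the whole embryo at 6063. There S100a6 was also highest in Ad replicate 2 (493.09), while Rgs2 was highest in Pp replicate 1 (494.7). On MOE430B Ad replicate 4 was above Ad replicate 3 in Esr1 (81.9 against 17.8) and Tdo2 (86.3 against 21.3). Pp replicates 3 and 4 were at 84.35 and 36.33 for Esr1, so Pp replicate 3 was the highest fragment. For Tdo2 they were at 42.09 and 37.66.

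Decidual genes stood out in the whole embryo. Of 20 further decidual stroma genes (0 of them in the other lists), 13 were measured on MOE430A and 9 were lower in the fragments with 0 higher; the median log2 difference was -0.887, a value that maternal decidual RNA in the whole-embryo sample would give, with Col3a1 at 2910 against 527 ± 144 and Acta2 at 4869 against 2061 ± 115. Extraembryonic ectoderm in the whole embryo cannot be told apart from it: in Pp replicate 2, where the median of its own genes reached 0.922 of their excess in the whole embryo, that of the decidual genes reached 0.0367, but this is 1 array, and its Hand1 was at 1248 against 4014. Scaling between arrays is argued against, since 8 of the 9 genes still passed after quantile normalization. Each array type had a single whole-embryo array, and part of the fall of the parietal endoderm, actin and lysosome lists could have the same source, which was not tested.

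Of the 18 measured extraembryonic ectoderm genes 15 were higher in Pp replicate 2 than in Pp replicate 1, with a median of 0.24. This lay at percentile 100 of 10000 random lists matched on signal (middle 95% from -0.07 to 0.09), so other genes of that signal did not share the difference, which argues against unlike signal of the arrays; the list was picked for this difference, so the percentile says nothing about chance. Over those genes the difference followed the excess of the whole embryo over Ad (Spearman rho 0.624), so a candidate explanation is extraembryonic ectoderm cells in this fragment, whose upper limit lay at the boundary of that tissue. Of the list's 22 genes 5 stand in another list, and epiblast also expresses some of them. A biological difference between the embryos dissected was not tested and stays open.

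Cholesterol synthesis genes leaned lower in Ad, with 0 of 13 past limma's threshold and the list's adjusted p at 0.255 with an estimated correlation. Without Pp replicate 2 the list median was -0.343, which argues against extraembryonic ectoderm in that array as the source. In Pp replicate 1 the median of the extraembryonic ectoderm genes reached 0.283 of their excess in the whole embryo. That tissue in Pp replicate 1 was not tested as a source. Under quantile normalization and cyclic loess the cholesterol list median nearest 0 was -0.288, which argues against scaling. Less visceral endoderm in the Ad fragments cannot be told apart from a change per cell: the general visceral endoderm list had a median of -0.0756 with 12 of 22 genes below 0, so its members go both ways. A difference between the regions stays open as a hypothesis.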
